A study of Homo sapiens with 24 samples.

How the data were processed

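Bulk RNA was measured in HCT116 colorectal cancer cells of 3 lines, p53 wild type (WT), p53 mutant (Mutant) and p53 null (Null). Each line received solvent, 20 uM APR-246, 6 Gy of irradiation, or the combination, with 2 libraries per group and 24 libraries in all. Cells grew in McCoy 5A medium with 10% FBS and were collected 72 hours after irradiation. RNA was taken with TRIzol, mRNA was selected with oligo(dT), and paired reads of 100 bases came from a BGIseq500. The labels number the replicates but do not state whether they are separate cultures, so every p-value measures only the spread between these samples.

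Per the submitters' processing notes, the authors used FastQC, STAR and featureCounts from Subread on GRCh38.p13, with no versions, annotation release or counting strand given. The deposited values are in CPM of all reads assigned to genes, with 60675 gene ids per library. The values of each library add up to the fixed total that this unit implies, and dividing by the smallest step gave back the count of reads per gene behind the deposited CPM: 100% of values were whole within 0.05 of a read. Totals were 53184139 to 58058729 reads per library. Even counts made up 74.5 to 81.5% of the values of 2 to 9 reads, so the mates of a pair seem to have been counted singly and the number of fragments is lower. A floor of 3 reads corresponds to 0.0517 to 0.0564 CPM, and would lie higher if 3 fragments were required. This floor and intervals of that kind hold counting error only.

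Gene ids were matched to symbols for 60419 ids and to GENCODE 29 for 58444 ids, from which coordinates, gene length and GC percent were taken. The annotation release of the authors may differ. Genes were kept by filterByExpr with a count minimum of 10, which left 20668. HSPA1A and HSPA1B are near-identical neighbours and EPB41L4A-AS1 is antisense to another gene, so their counts are uncertain.

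The test planned before the data were examined was the edgeR quasi-likelihood test on counts. Because the deposited unit is CPM, the main test became limma-trend with robust variance estimation (limma 3.58.1, edgeR 4.0.16, R 4.3.3). It was run on log2 of TMM-scaled CPM plus 0.5, with 1 coefficient for each of the 12 groups and 12 residual degrees of freedom. On that scale fold changes of weakly expressed genes are understated. The edgeR test on the recovered counts is given as an alternative and called 1 gene higher and 5 lower for APR-246 in Null, 161 and 87 for irradiation in WT, 5 and 0 in Mutant, and 43 and 30 in Null. A gene was called at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The median standard error of a log2 difference was 0.32 between 2 groups and 0.45 for a difference of differences.

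Comparisons fixed before the data were examined were each treatment alone against solvent, the combination against irradiation, the departure of the combination from the sum of both effects ("beyond additive"), these responses in WT or Mutant minus Null, and the solvent groups between lines. Groups came from the labels alone, and no library was left out of the main tests. The labels record no sequencing date or batch. Each p53 status is represented by a single line, so a difference between lines cannot be separated from an effect of p53 status.

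Within each library, the slope of the log2 values on gene GC percent was computed over genes with a mean log2 CPM of at least 2, after centring each gene over the libraries (98.3% of tested genes have a GC value). A second limma model with this slope as a covariate (11 residual degrees of freedom) was chosen after seeing the data, as were all other settings that use GC content. Its values are printed as "with the GC slope" beside those of the main test. Both models were tested on simulated data: 200 of the 20668 genes were given a 2-fold or 4-fold change in the WT irradiation comparison. Without the GC slope limma recovered 1% of the 2-fold and 52% of the 4-fold changes with 0 false calls. With it, limma recovered 84% and 100% with 8 false calls, and edgeR did so with 10. The simulated counts were drawn from the fitted GC slope model, so the gain from the slope was fixed in advance.

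A total of 22 gene lists written from general knowledge before the data were examined were tested with camera from limma in 20 comparisons, which makes 440 tests adjusted together. The preset correlation between genes was 0.01, and the test was repeated with a correlation estimated for each list. The lists cover p53 targets, ATF4 and the integrated stress response, interferon-stimulated genes, DNA replication, G2/M, homologous recombination, replication-dependent histones, heat shock, endoplasmic reticulum chaperones, cholesterol synthesis, NF-kB and cytokines, glycolysis and hypoxia, NRF2 and glutathione, metallothioneins, ribosome biogenesis, antigen presentation, ferroptosis regulators, the BCL2 family, intestinal epithelium, blood cell markers, fibroblast markers and mitochondrially encoded mRNAs. Lists needed at least 5 tested members. Ferroptosis regulators and the BCL2 family were also tested for change in either direction with fry. Lists of WNT targets, YAP targets and spliced hosts of small nucleolar RNAs were added after seeing the data. In the simulated data camera called a list of 30 genes raised 2-fold (adjusted p 2.81e-30) and 0 of 20 random lists. Genes were drawn independently there, so this cannot show how often lists of genes that move together are called falsely.

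Named genes are the up to 5 largest called changes per direction with a mean log2 CPM of at least 2 and no overlap between the libraries of both groups, plus CDKN1A, MDM2 and leading list members. Some genes chosen this way are not printed. Y-linked genes, pseudogenes and genes with clone-based names were left out. Alternatives were DESeq2 1.42.0, edgeR quasi-likelihood in a pair of versions, other scaling, filters and pseudocounts, the libraries of the compared lines alone, replicate numbers as a block, leaving out each library in turn, and the GC settings.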

Results

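The data cover 3 HCT116 lines (WT, Mutant and Null for p53) under solvent, APR-246, irradiation or both, with 2 libraries per group and 53184139 to 58058729 reads per library. Irradiation switched on the p53 programme in WT cells. In WT cells CDKN1A, the inhibitor of cyclin-dependent kinases that holds damaged cells in arrest, reached 4.06-fold its solvent level 72 hours after exposure. TP53I3, PLK2 and BTG2, further p53 targets, rose with it. CDC25C, a phosphatase that drives entry into mitosis, fell. CDKN1A (chromosome 6, 36676460 to 36687339) went from 545 ± 52.1 CPM to 2207 ± 64.2 CPM (log2 2.02 ± 0.40, adjusted p = 0.019). That call was lost without WT solvent library 1 (1.61) or WT irradiation library 2 (1.79) and from the WT libraries alone, and kept with the GC slope. TP53I3 rose by 2.71 ± 0.41 (adjusted p = 0.00346), PLK2 by 2.14 ± 0.33 (adjusted p = 0.0039) and BTG2 by 1.86 ± 0.31 (adjusted p = 0.00797). CDC25C changed by -1.29 ± 0.27 (adjusted p = 0.025). MDM2 (chromosome 12, 68808176 to 68850686), the ubiquitin ligase that limits p53, was 1.06 ± 0.58 (adjusted p = 0.517), and rose by 1.49 ± 0.17 with the GC slope (adjusted p = 4.35e-06).

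**Figure D1:**
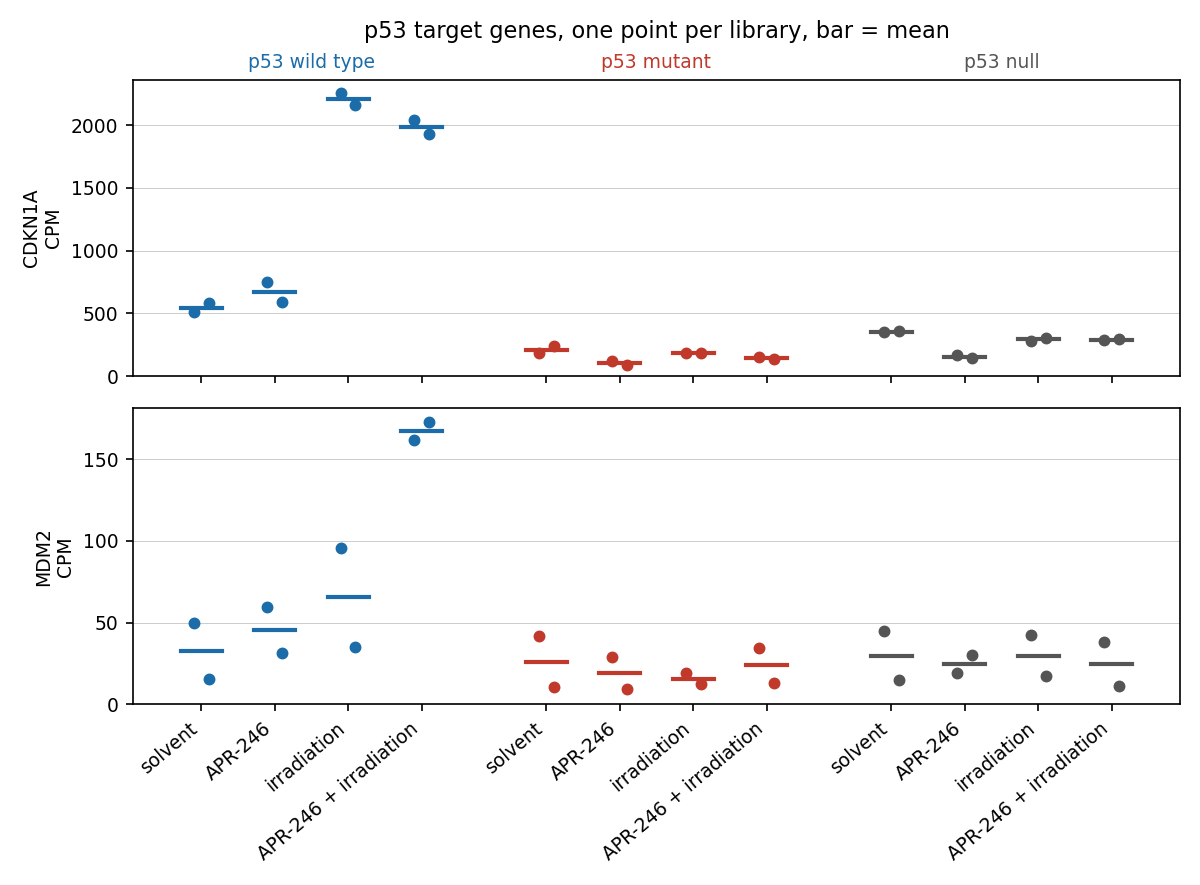
CPM of CDKN1A and MDM2 in each library (points) with the group mean of 2 libraries (bar), by line and treatment. CDKN1A stands high only in the irradiated WT groups.

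The p53 target list of 39 genes rose in WT after irradiation, with a median log2 change of 1.05 (adjusted p = 1.33e-15, and adjusted p = 8.39e-05 with an estimated correlation). Of its genes 9 rose and 0 fell over all genes tested. Adjusted over the list alone, 20 rose and 1 fell. In Mutant the median was 0.09 (adjusted p = 0.475) and in Null -0.07 (adjusted p = 0.268), and no member was called there. In Mutant PLK2 (1.15 ± 0.13, adjusted p = 4.11e-05) and BTG2 (0.95 ± 0.28, adjusted p = 0.0335) rose once the GC slope was added, while CDKN1A fell in Null (-0.52 ± 0.16, adjusted p = 0.0208), a call lost without any 1 of its 4 libraries but Null irradiation library 2. The change of this list in WT exceeded that in Null by a median of 1.07 (adjusted p = 1.98e-29, and adjusted p = 4.42e-06 with an estimated correlation). Mutant exceeded Null by 0.18 (adjusted p = 0.0119, but adjusted p = 0.102 with an estimated correlation).

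Gene by gene, the change after irradiation in WT minus that in Null was called above 0 for 6 genes and below 0 for 0. In this limma test 624 genes had an unadjusted p below 0.05. With replicate numbers as a block 20 genes were called. All 6 genes of the test without a block are expressed below a mean log2 CPM of 2. The p53 target SPATA18 (WT 0.126 CPM in solvent and 0.891 CPM after irradiation) is one of them, with a difference of 1.29 ± 0.20 (adjusted p = 0.0322). The count was 31 without WT irradiation library 1, 0 to 2 without any 1 of the other 7 libraries, 20 by DESeq2 and 0 by edgeR. In the model with the GC slope 170 genes had a difference above 0 and 59 below 0, whatever the size of each response, a total of 229 that was 84 to 162 without any 1 of the 8 libraries (84 without Null irradiation library 1). CDKN1A (2.31 ± 0.22, adjusted p = 4.34e-06), TP53I3 (2.23 ± 0.27, adjusted p = 0.000146) and MDM2 (1.40 ± 0.24, adjusted p = 0.00261) were among the first. CDC25C (-1.40 ± 0.24, adjusted p = 0.00346) and the ephrin EFNB2 (-1.60 ± 0.23, adjusted p = 0.000674) were among the second. SUSD2, ZBED2 and KLK5 had the largest differences besides CDKN1A, at 2.72, 2.63 and 2.41. No gene differed between Mutant and Null in limma (412 at unadjusted p below 0.05; 0 by DESeq2 and by edgeR), and 1 did without Null solvent library 1. With the GC slope 1 gene did, the matrix protein SPARC (-2.03 ± 0.31, adjusted p = 0.0283). That count was 3 without Null solvent library 2 and 0 without any 1 of the other 7.

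Outside the p53 programme, the largest changes in irradiated WT cells were in these single genes. GALNT5, which starts mucin-type glycosylation, and the carboxypeptidase CPA4 rose, as did the protease KLK5. The largest falls were in the cytokine receptor chain IL20RB, the stress-induced NIBAN1, the uridine phosphorylase UPP1 and the calcium channel TRPV6. Over all genes 200 were higher and 122 lower. GALNT5 rose by 3.73 ± 0.47 (adjusted p = 0.000847), CPA4 by 2.76 ± 0.25 (adjusted p = 3.62e-05) and KLK5 by 3.96 ± 0.70 (adjusted p = 0.011). KRTAP2-3 (3.19) and the cilia regulator FOXJ1 (3.04) were among the largest rises as well. IL20RB was at -3.88 ± 0.74 (adjusted p = 0.0164), NIBAN1 at -3.78 ± 0.69 (adjusted p = 0.0138), UPP1 at -3.61 ± 0.85 (adjusted p = 0.0448), TRPV6 at -3.18 and RBCK1 at -3.12. The calls of GALNT5, CPA4 and KRTAP2-3 were kept without any 1 of the 4 libraries. KLK5 lost its call without WT solvent library 1 (3.34) or WT irradiation library 2 (3.24), FOXJ1 without any but WT solvent library 2, and each of the 5 genes that fell without any 1 of the 4. The total of 322 was 67 without WT solvent library 2, 73 without WT irradiation library 2, 96 without WT solvent library 1 and 155 without WT irradiation library 1. It was 0 from the WT libraries alone, 1611 with replicate numbers as a block (1249 with a block per line) and 3724 with the GC slope (1081 without WT solvent library 2, up to 3018 without WT solvent library 1).

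In Null cells irradiation raised the antiviral gene IFIT1, the growth factor BMP4, the carbonic anhydrase CA2 and the kinase SGK1. It lowered DDIT4, an inhibitor of mTORC1, STC2, PSAT1 of serine synthesis and the glucocorticoid-induced TSC22D3. IFIT1 rose by 2.64 ± 0.25 (adjusted p = 0.000212), CA2 by 2.29 ± 0.27 (adjusted p = 0.00284), BMP4 by 2.34 ± 0.40 (adjusted p = 0.023), SGK1 by 1.83 ± 0.25 (adjusted p = 0.00548) and HSPA1B by 2.31 ± 0.43 (adjusted p = 0.0293). DDIT4 was at -3.17 ± 0.51 (adjusted p = 0.02), STC2 at -2.97 ± 0.64 (adjusted p = 0.0465), TSC22D3 at -2.84 ± 0.44 (adjusted p = 0.0181), the cytokine receptor IL21R at -2.30 and PSAT1 at -2.26. Only IFIT1 kept its call without any 1 of the 4 libraries. CA2 lost it without Null irradiation library 2 (2.38), SGK1 without any but Null solvent library 2, and each of the other genes named here without any 1 of the 4, HSPA1B included. In all 85 genes were higher and 55 lower; the total of 140 was 1 to 12 without any 1 of its 4 libraries (1 without Null irradiation library 2), 1305 with replicate numbers as a block (951 with a block per line) and 4133 with the GC slope (1526 without Null irradiation library 1, up to 2294 without the other).

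Irradiated Mutant cells shared the rise of CA2 and also raised the choline kinase CHKA, the receptor FGFR3 and CRISPLD2. A pair of spliced hosts of small nucleolar RNAs, SNHG8 and EPB41L4A-AS1, fell. Here 14 genes were higher and 2 lower by limma, against 5 and 0 by edgeR, the test planned first. CA2 rose by 1.98 ± 0.27 (adjusted p = 0.0179), CHKA by 1.65 ± 0.29 (adjusted p = 0.0453), FGFR3 by 1.62 ± 0.27 (adjusted p = 0.0453) and CRISPLD2 by 1.40 ± 0.25 (adjusted p = 0.0471). EPB41L4A-AS1, whose antisense position leaves its count uncertain, was at -2.29 ± 0.40 (adjusted p = 0.0453) and SNHG8 at -2.10 ± 0.36 (adjusted p = 0.0453). Each of these 6 genes lost its call without any 1 of the 4 libraries. With replicate numbers, which pair libraries across groups, as a block the total of 16 became 2416, and 1692 with a block per line. It was 0 without Mutant solvent library 1 or either irradiated Mutant library, 2 without Mutant solvent library 2 and 2786 with the GC slope (325 without Mutant solvent library 2, up to 2040 without Mutant solvent library 1).

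Called genes were shared between lines beyond the number expected by overlap of unrelated lists. WT and Null shared 23 genes higher after irradiation (0.823 expected, adjusted p = 1.59e-26, Fisher's exact test) and 25 lower (0.325 expected, adjusted p = 4.42e-41). Mutant and Null shared 7 higher (0.0576 expected, adjusted p = 2.07e-13) and 2 lower (0.00532 expected, adjusted p = 1.67e-05), SNHG8 and EPB41L4A-AS1 being the only lower genes in Mutant. WT and Mutant shared 5 higher (0.135 expected, adjusted p = 4.53e-07) and 0 lower (0.0118 expected). Shared counts above 0 fell with every library left out: WT and Null shared 1 higher without Null irradiation library 2 and 9 without WT solvent library 1 or WT irradiation library 1. WT and Mutant shared 0 without any 1 of their 8 libraries. Genes are not independent replicates in such tests.

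The interferon programme rose as a list after irradiation in all 3 lines. IFIT1, IFIT2, IFI6 and IFI27, genes of the antiviral state, led it in WT. The list of 30 genes had medians of 0.78 in WT (adjusted p = 1.8e-12), 0.38 in Mutant (adjusted p = 1.62e-07) and 0.74 in Null (adjusted p = 2.05e-11). These calls held with an estimated correlation (adjusted p = 0.00456, 0.0249 and 0.00557) and were lost when the GC slope was added to that test (adjusted p = 0.0688, 0.0789 and 0.0688). Over all genes 5, 0 and 2 members rose, and adjusted over the list alone 13, 9 and 11. IFIT1 (chromosome 10, 89392546 to 89406486) went from 1.5 ± 0.487 to 10.9 ± 0.239 CPM in WT (log2 2.56 ± 0.25, adjusted p = 6.44e-05). After APR-246 alone the list was not called (adjusted p = 0.193, 0.876 and 0.238 in WT, Mutant and Null); irradiation and APR-246 were not compared directly.

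Genes of the ATF4 programme, which cells induce when amino acids run short or proteins misfold, were on average higher in solvent than after APR-246 or irradiation in each line, though WT APR-246 library 1 stayed at the solvent level. DDIT4, CHAC1, which breaks down glutathione, and the asparagine synthetase ASNS follow this course. DDIT4 (chromosome 10, 72273920 to 72276036) fell after irradiation from 429 ± 109 to 63.1 ± 2.49 CPM in WT (-2.73 ± 0.51, adjusted p = 0.0151) and from 474 ± 120 to 58.3 ± 13.5 CPM in Null. CHAC1 (chromosome 15, 40952962 to 40956519) was at 206 ± 92.7 CPM in WT solvent and 22.5 ± 9.07 CPM after irradiation (-3.15 ± 0.79, adjusted p = 0.0578). ASNS (chromosome 7, 97852118 to 97872542) fell from 12 ± 1.07 to 1.28 ± 0.164 CPM (-2.82 ± 0.66, adjusted p = 0.0442). The list of 28 genes had medians after irradiation of -1.80 in WT (adjusted p = 1.4e-20), -1.46 in Mutant (adjusted p = 1.22e-12) and -1.93 in Null (adjusted p = 5.52e-23). None held with an estimated correlation (adjusted p = 0.176, 0.246 and 0.145). Over all genes 7, 0 and 5 members fell, and adjusted over the list alone 21, 20 and 23.

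**Figure D2:**
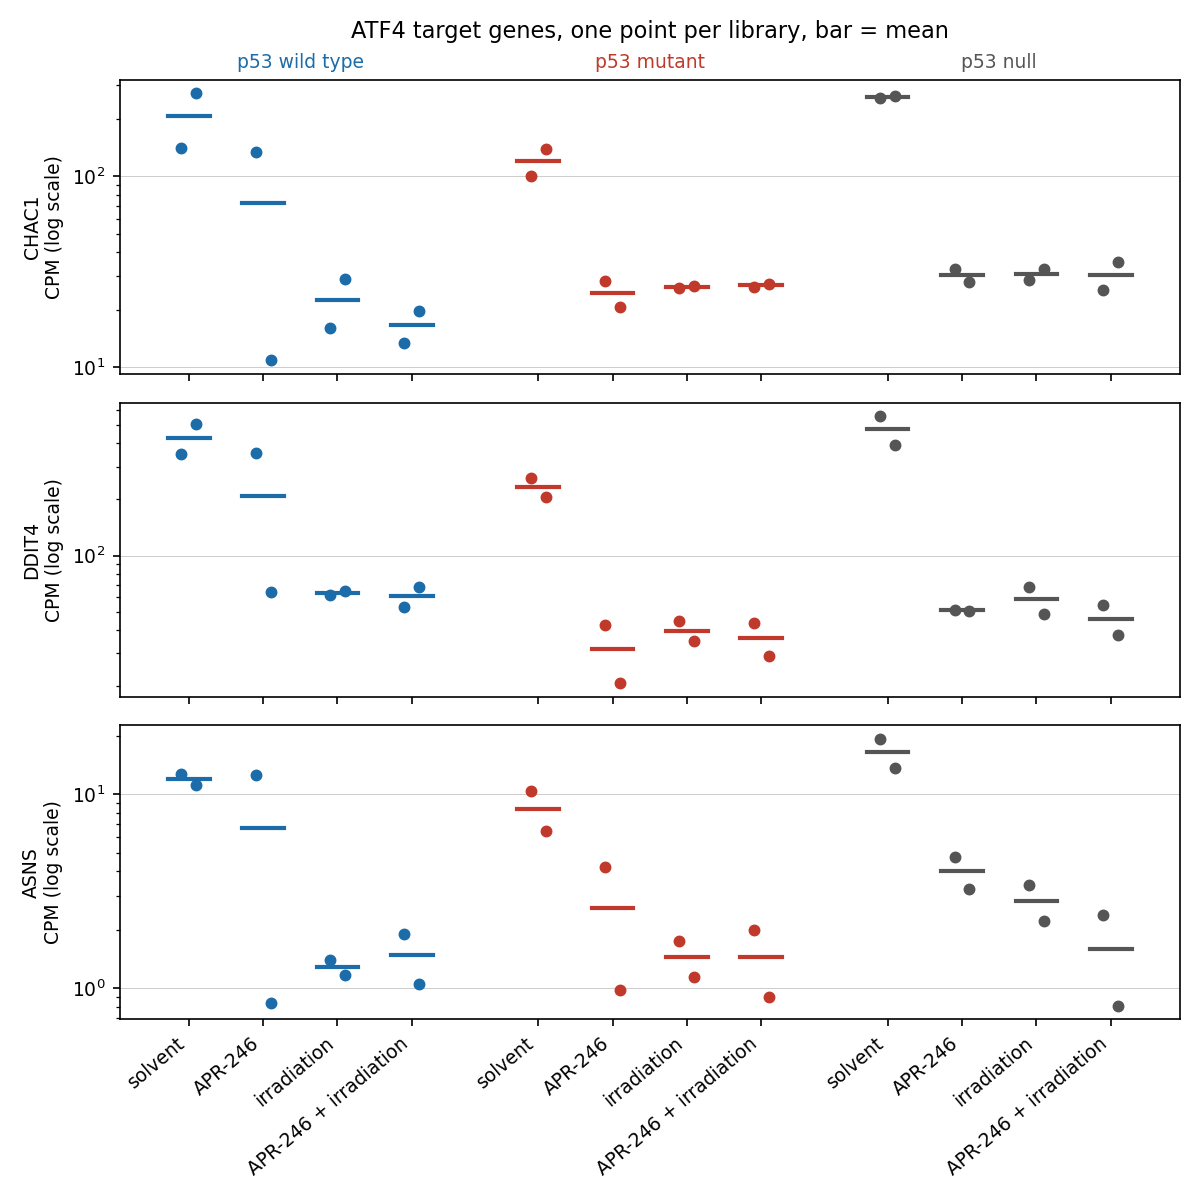
CPM of CHAC1, DDIT4 and ASNS on a log axis in each library (points) with the group mean of 2 libraries (bar), by line and treatment. All 3 genes are highest in solvent, and one WT APR-246 library stays at the solvent level.

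In Null cells after APR-246 alone BMP4 and CA2 rose, and DDIT4 and TSC22D3 fell, as they did after irradiation; both comparisons use the same solvent libraries, so a shared response was not separated from a shift of those. The iron-binding LCN2, the growth factor HBEGF and the stress-induced transcription factor ATF3 fell as well. BMP4 rose by 2.32 ± 0.40 (adjusted p = 0.0421), CA2 by 1.84 ± 0.27 (adjusted p = 0.016), the intermediate filament gene NES by 1.73 (adjusted p = 0.0421) and SCD5 by 1.24 ± 0.23 (adjusted p = 0.0498). LCN2 was at -3.82 ± 0.71 (adjusted p = 0.0498), DDIT4 at -3.35 ± 0.51 (adjusted p = 0.0194), TSC22D3 at -3.11 ± 0.44 (adjusted p = 0.016), HBEGF at -2.41 ± 0.43 (adjusted p = 0.0498) and ATF3 at -2.34 ± 0.36 (adjusted p = 0.0194). Each of these genes lost its call without any 1 of the 4 libraries. In all 6 genes were higher and 21 lower; the total of 27 was 0 without Null APR-246 library 2, 1 without Null APR-246 library 1 or Null solvent library 1, 5 without Null solvent library 2, 567 with replicate numbers as a block (305 with a block per line) and 3101 with the GC slope (854 without Null APR-246 library 2, up to 1779 without Null APR-246 library 1). That model adds the WNT feedback gene AXIN2 (2.72, adjusted p = 0.0106) and CHAC1 (-3.23, adjusted p = 0.0225). CHAC1 lost that call without any 1 of the 4 libraries, and AXIN2 without any but Null APR-246 library 1.

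In Mutant cells genes of DNA replication were higher after APR-246 as a list by the preset test, a call lost with an estimated correlation (adjusted p = 0.0597), and no gene passed in limma without the GC slope or a replicate block. With replicate numbers as a block 299 genes passed, and 57 with a block per line; without a filter on low counts 14 did. Without block or slope 1516 genes had an unadjusted p below 0.05, DESeq2 called 101 and edgeR called 0, and limma called 8 without Mutant APR-246 library 1. Adding the GC slope, 693 genes were higher and 720 lower, and 0 were called without Mutant solvent library 2 or Mutant APR-246 library 2. The replication factors MCM4 (1.81 ± 0.33, adjusted p = 0.0103) and GINS2 (1.89 ± 0.36, adjusted p = 0.0117) and the kinase inhibitor CDKN2C (1.87 ± 0.36, adjusted p = 0.0103) rose in that model. DDIT4 (-2.92 ± 0.56, adjusted p = 0.0156), SESN2 (-2.41 ± 0.60, adjusted p = 0.0372) and the keratins KRT7 (-2.20) and KRT16 (-2.17) fell. KRT7 lost that call without any 1 of the 4 libraries, SESN2 without any but Mutant APR-246 library 1, and the others without Mutant solvent library 2 or Mutant APR-246 library 2.

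In WT cells no gene was called after APR-246 by limma (557 at unadjusted p below 0.05), DESeq2 (657) or edgeR, and 0 with the GC slope. The 2 libraries of this group differ: ATF4 targets stood -0.149 from the mean of WT solvent in library 1 and -2.22 in library 2. Without library 1 limma called 132 genes, and 2852 with the GC slope; without WT solvent library 1 it called 1 and 7. CDKN1A was 671 ± 112 CPM after APR-246 (0.18 ± 0.40, adjusted p = 1).

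By the preset test, ATF4 targets and NF-kB targets were lower after APR-246 than in solvent in all 3 lines. Replication, heat shock and cholesterol genes were higher. Values below are in the order WT, Mutant, Null. The irradiation comparisons of each line use the same solvent libraries, so an effect of APR-246 was not separated from a shift of those. ATF4 medians were -1.19, -1.33 and -1.75 (adjusted p = 2.04e-24, 6.88e-16 and 9.54e-24; with an estimated correlation adjusted p = 0.143, 0.206 and 0.143). Over all genes 0, 0 and 2 members fell, and adjusted over the list alone 0, 13 and 21. The WT median rests on WT APR-246 library 2: the list stood -0.149 from the mean of WT solvent in library 1 and -2.22 in library 2, against -0.197 and 0.197 in the solvent libraries. Over 945 genes called in the same direction in Mutant and Null with the GC slope, library 1 showed 15% of the shift of library 2, so the WT values of the other lists also come from unlike libraries. NF-kB medians were -0.31, -0.35 and -0.47 (adjusted p = 6.29e-08, 0.000175 and 1.87e-07; adjusted p = 0.143, 0.245 and 0.145 with an estimated correlation). Replication medians were 0.47, 1.17 and 0.77 (adjusted p = 1.41e-10, 3.82e-31 and 6.78e-15; adjusted p = 0.245, 0.0597 and 0.204 with an estimated correlation). In Mutant 0 of the 33 replication genes rose over all genes and 22 adjusted over the list alone. Heat shock medians were 0.28, 0.74 and 0.79 (adjusted p = 0.0119, 1.16e-08 and 1.63e-06; adjusted p = 0.437, 0.0891 and 0.145 with an estimated correlation). Cholesterol synthesis stood at 0.58, 0.71 and 0.54 (adjusted p = 5.28e-08, 2.55e-06 and 0.00184; adjusted p = 0.204, 0.245 and 0.488 with an estimated correlation).

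The p53 target list responded to APR-246 differently by line in the preset test. The lines also differed in solvent, so an effect of p53 status was not separated from other differences between them. In WT its median was 0.18 (adjusted p = 0.00857, adjusted p = 0.0891 with an estimated correlation), in Mutant 0.02 (adjusted p = 0.714) and in Null -0.16 (adjusted p = 0.0224, adjusted p = 0.143 with an estimated correlation). No member was called over all genes; adjusted over the list alone 1 rose in WT and 6 fell in Null. The difference between WT and Null was 0.54 (adjusted p = 2.45e-08) and between Mutant and Null 0.31 (adjusted p = 0.000453). Both held with an estimated correlation (adjusted p = 0.00173 and 0.0257), and only the first when the GC slope was added to that test (adjusted p = 0.0241 and 0.0822). Of single genes 0 differed between WT and Null in limma (286 at unadjusted p below 0.05), DESeq2 and edgeR, and 3 did without WT APR-246 library 2 (1 without Null solvent library 1 or Null APR-246 library 1). In the GC slope model CDKN1A (1.57 ± 0.22, adjusted p = 0.0035) and the immune checkpoint gene VSIR (1.73 ± 0.22, adjusted p = 0.00134) did, and without WT APR-246 library 2 that count of 2 was 778. CDKN1A lost this call without WT solvent library 1 (1.48) or Null APR-246 library 2 (1.46). In that model CDKN1A fell after APR-246 in Mutant (-1.13, adjusted p = 0.00285) as in Null (-1.37, adjusted p = 4.54e-05), the Mutant call being lost without Mutant solvent library 2 or Mutant APR-246 library 2. In Null cells CDKN1A was 353 ± 6.71 CPM in solvent and 153 ± 17.8 CPM after APR-246, and VSIR 99.2 ± 7.53 and 36.9 ± 6.07 CPM. In WT cells VSIR was 28.2 ± 9.58 and 32.5 ± 4.31 CPM. Between Mutant and Null 0 genes differed in limma (257 at unadjusted p below 0.05), in DESeq2 and in edgeR, with 2 without Mutant APR-246 library 1 and 1 without Null solvent library 1 or Null APR-246 library 1.

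**Figure D3:**
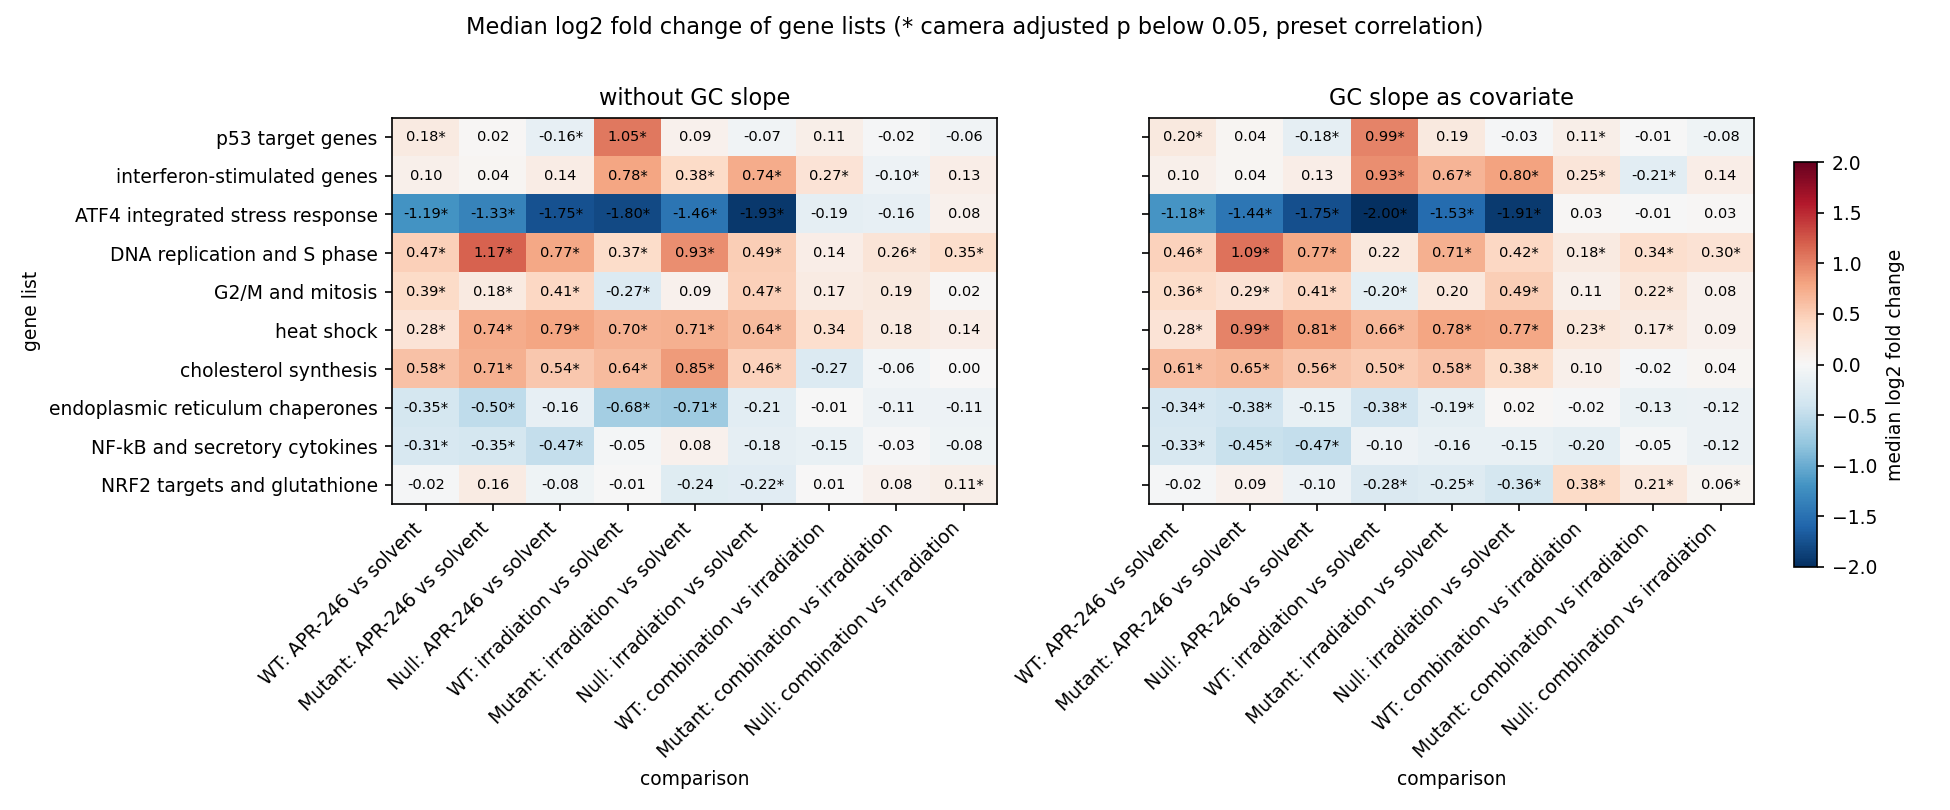
Median log2 change of 10 gene lists (vertical) in 9 comparisons (horizontal), without and with the GC slope, with a star where camera with the preset correlation gives an adjusted p below 0.05. ATF4 targets are lower than in solvent after APR-246 and after irradiation, and p53 targets rise strongly only in irradiated WT cells.

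Other lists followed irradiation too (WT, Mutant, Null). Heat shock genes rose, with HSPA1B and HSPA1A (1.97 ± 0.42, adjusted p = 0.043) passing in Null though reads of these near-identical genes cannot be assigned with certainty; medians were 0.70, 0.71 and 0.64 (adjusted p = 0.000415, 4.06e-05 and 2.84e-05; adjusted p = 0.245, 0.204 and 0.204 with an estimated correlation). Replication-dependent histone genes, whose polyadenylated transcripts appear when cells leave the cycle, stood at 0.49, 0.66 and 0.45 (adjusted p = 0.000195, 1.98e-06 and 0.000415; adjusted p = 0.216, 0.143 and 0.238 with an estimated correlation). Replication genes were at 0.37, 0.93 and 0.49 (adjusted p = 0.0221, 4.33e-14 and 2.05e-06; adjusted p = 0.729, 0.204 and 0.438 with an estimated correlation). Cholesterol genes were at 0.64, 0.85 and 0.46 (adjusted p = 0.000196, 6.43e-06 and 0.048; adjusted p = 0.372, 0.248 and 0.677 with an estimated correlation). Mitotic genes of the G2/M list were lower in WT at -0.27 (adjusted p = 0.0287, adjusted p = 0.556 with an estimated correlation) and higher in Null at 0.47 (adjusted p = 0.000856, adjusted p = 0.326 with an estimated correlation). WT differed from Null by -0.76 (adjusted p = 6.35e-11, adjusted p = 0.0764 with an estimated correlation). Chaperones of the endoplasmic reticulum fell in WT, with HERPUD1 (-1.34 ± 0.29, adjusted p = 0.029) and HYOU1 (-1.64 ± 0.37, adjusted p = 0.036) passing, and in Mutant; medians were -0.69 and -0.71 (adjusted p = 2.16e-05 and 0.0461; adjusted p = 0.0597 and 0.324 with an estimated correlation).

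Lists called in fewer comparisons were these. Metallothioneins were at -1.0 in irradiated WT (adjusted p = 0.0404, adjusted p = 0.532 with an estimated correlation). NRF2 and glutathione genes were at -0.22 and ribosome biogenesis at -0.27 in irradiated Null (adjusted p = 0.0132 and 0.0114; adjusted p = 0.273 and 0.143 with an estimated correlation). Glycolysis and hypoxia genes were at 0.61 in WT after APR-246 (adjusted p = 6.09e-06, adjusted p = 0.206 with an estimated correlation). Homologous recombination was at 0.26, 0.38 and 0.26 after APR-246 (adjusted p = 0.0157, 0.00119 and 0.0226; adjusted p = 0.705, 0.646 and 0.729 with an estimated correlation). Ferroptosis regulators, the BCL2 family, intestinal epithelium and fibroblast markers were called in none of the 20 comparisons. The fry test in either direction gave adjusted p values of 0.753 to 0.787 for the first pair without the GC slope. With it that test passed in several comparisons, such as irradiated WT (7.53e-06 for ferroptosis regulators and 3.79e-05 for the BCL2 family), irradiated Null (4.84e-05 and 0.000181) and Mutant against Null in solvent (1.63e-08 and 0.000139), while camera called neither list. The fry test asks whether list genes change at all, not whether they change more than other genes. With the GC slope 3724, 4133 and 3264 of all 20668 genes were called in these comparisons. Single members passed in irradiated WT: ALOX5, a lipid-oxidising enzyme (2.23 ± 0.38, adjusted p = 0.0081), and CEACAM1 (2.24 ± 0.31, adjusted p = 0.0018). In all, 126 of the 440 list tests were called, 9 with an estimated correlation as well, and the median, the mean and the test had the same sign in each of the 126.

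No single gene was called by limma in any line when APR-246 was added to irradiation. CDKN1A stayed at the level of irradiation alone in WT, 1987 ± 80.4 CPM in the combination (-0.42 ± 0.40, adjusted p = 0.785). MDM2 averaged 65.6 ± 43 CPM after irradiation and 167 ± 7.97 CPM in the combination, a difference not called over all genes (1.25 ± 0.58, adjusted p = 0.785). DDIT4 and CHAC1, low after irradiation, did not fall further. Counts were 0 by limma in WT, Mutant and Null (849, 405 and 345 at unadjusted p below 0.05) and by edgeR, and 1, 0 and 0 by DESeq2, while limma without a filter on low counts called 30, 28 and 58. The GC slope left them at 0 (2425, 1625 and 1603). Without WT irradiation library 1 limma called 47 genes in WT, and without WT combination library 1 it called 1 (48 and 51 with the GC slope). Between the lines 0 genes differed (382 for WT minus Null and 267 for Mutant minus Null at unadjusted p below 0.05; 0 by DESeq2 and edgeR), with 22 for WT minus Null without WT irradiation library 1.

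Some lists moved in the combination against irradiation. Interferon genes rose further in WT, as a list (IFIT1 23.7 ± 0.675 CPM against 10.9 ± 0.239 CPM, adjusted p = 0.785), and replication genes rose in Mutant and Null. The interferon median was 0.27 in WT (adjusted p = 0.0066, adjusted p = 0.204 with an estimated correlation) and -0.10 in Mutant (adjusted p = 0.0487, adjusted p = 0.342 with an estimated correlation). Replication stood at 0.26 in Mutant and 0.35 in Null (adjusted p = 0.000167 and 1.33e-07; adjusted p = 0.56 and 0.371 with an estimated correlation). Antigen presentation fell in WT and Mutant, each at -0.46 (adjusted p = 0.0225 and 0.000288; adjusted p = 0.66 and 0.438 with an estimated correlation). Homologous recombination was at 0.48 in WT and 0.31 in Mutant (adjusted p = 0.0334 and 0.0111; adjusted p = 0.732 and 0.705 with an estimated correlation). The WT calls of antigen presentation and homologous recombination turned in sign with the GC slope (adjusted p = 0.797 and 0.432). ATF4 targets were at -0.19, -0.16 and 0.08 (adjusted p = 0.423, 0.256 and 0.617) and p53 targets in WT at 0.11 (adjusted p = 0.133).

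Against the sum of both effects, the combination departed for some lists by the preset test, none of which held with an estimated correlation, and for single genes mainly in Null with the GC slope. ATF4 targets lay above the sum in every line, and replication and cholesterol genes lay below it. ATF4 targets moved little and were not called in the combination against irradiation. Their departure therefore largely mirrors the opposite change after APR-246 alone, which in WT rests on WT APR-246 library 2. In Null cells, in the GC slope model, ATF3 and TSC22D3 lay above the sum and BMP4, BMP6 and the transcription factor SOX4 below. ATF4 medians were 1.11, 1.23 and 1.69 in WT, Mutant and Null (adjusted p = 5.28e-08, 5.62e-09 and 4.57e-21; adjusted p = 0.434, 0.372 and 0.17 with an estimated correlation). Replication medians were -0.39, -0.97 and -0.47 (adjusted p = 0.00344, 2.48e-14 and 0.000209; adjusted p = 0.67, 0.204 and 0.576 with an estimated correlation), and cholesterol medians -0.84, -0.81 and -0.32 (adjusted p = 2.25e-05, 2.82e-06 and 0.0232; adjusted p = 0.289, 0.245 and 0.646 with an estimated correlation). By gene 0 were called by limma in the 3 lines (640, 766 and 946 at unadjusted p below 0.05) and by edgeR, and 0, 0 and 26 by DESeq2. With replicate numbers as a block limma called 2 in Null. Without WT irradiation library 1 the WT count was 21, without WT APR-246 library 1 it was 9 and without WT combination library 1 it was 1. Without Mutant APR-246 library 1 the Mutant count was 3, and without Null APR-246 library 1 the Null count was 1. With the GC slope 370 genes were above and 337 below the sum in Null, 0 in WT and 0 in Mutant. The Null total of 707 was 0 without Null irradiation library 1 and 53 to 575 without any 1 of the other 7 libraries, and the WT count was 1431 without WT APR-246 library 1. ATF3 (2.46 ± 0.48, adjusted p = 0.0192), TSC22D3 (2.83 ± 0.66, adjusted p = 0.0375), CDKN1A (1.40 ± 0.22, adjusted p = 0.00545), BMP6 (-2.20 ± 0.37, adjusted p = 0.00605), BMP4 (-2.10 ± 0.53, adjusted p = 0.0486) and SOX4 (-1.87 ± 0.33, adjusted p = 0.00983) were among them. BMP4 and TSC22D3 lost the call without any 1 of the 8 libraries and ATF3 without 7 of them, SOX4 without Null APR-246 library 1 or Null irradiation library 1, and CDKN1A and BMP6 without Null irradiation library 1.

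How the effect of APR-246 alone relates to its effect on top of irradiation was left undetermined, over 10744 genes that are not independent replicates. Pearson's r was 0.078 in WT, -0.199 in Mutant and 0.118 in Null (Spearman's rho 0.0736, -0.261 and 0.113). In WT r was -0.743 without WT solvent library 2, -0.346 without WT APR-246 library 1, 0.732 without WT solvent library 1 and 0.739 without WT APR-246 library 2. In Mutant it ran from -0.497 without Mutant solvent library 2 to 0.428 without Mutant solvent library 1, and in Null from -0.218 to 0.396 without the solvent libraries 1 and 2 in turn. With the GC slope r in Mutant was 0.267. No sign or size of this relation is therefore given.

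The lines also differed before any treatment. PXDN, a peroxidase of the extracellular matrix, was nearly silent in Null and expressed in both other lines, while the secreted FGFBP1 was highest in Null. Relative to Null, WT had more DYSF and EHF and less of the YAP target CCN2 and of the WNT inhibitor DKK1. Mutant had more SEMA3A, VCAN and ETV1 and less SPRR2D, CALB2 and MAL2. PXDN (chromosome 2, 1631887 to 1744852) was 23.6 ± 11.8 CPM in WT, 38.9 ± 14.3 CPM in Mutant and 0.177 ± 0.00453 CPM in Null. It is 1 of 3 of the 5 largest differences above Null in WT that are given here, with DYSF (4.33 ± 0.43, adjusted p = 3e-05) and EHF (4.11 ± 0.47, adjusted p = 0.000174). CCN2 was at -3.40 ± 0.27 (adjusted p = 2.92e-06), DKK1 at -3.16 ± 0.30 (adjusted p = 1.38e-05), and LNCAROD at -4.31 and ZBED2 at -3.71. In Mutant SEMA3A was at 6.15 ± 0.58 (adjusted p = 1.37e-05), VCAN at 3.92 ± 0.56 (adjusted p = 0.000753), SPRR2D at -6.06 ± 0.71 (adjusted p = 0.000139) and FGFBP1 at -4.52 ± 0.36 (adjusted p = 2.04e-06). WT had 129 genes higher and 76 lower than Null, and Mutant differed in 515, of which 267 were lower. The total of 515 was 202 to 368 without any 1 of its 4 libraries (202 without Null solvent library 2), and the WT total of 205 was 104 to 157 (104 without Null solvent library 2). Other settings raised the totals of WT and Mutant, to 464 and 962 by DESeq2, 568 and 1501 with replicate numbers as a block, and 1788 and 3264 with the GC slope. Both totals with the GC slope were lower without any 1 of their 4 libraries.

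Some single inflammatory genes and the interferon list separated the untreated lines as well. IGFBP3 (4.30 ± 0.29, adjusted p = 3.1e-07), ICAM1 (3.76 ± 0.35, adjusted p = 1.2e-05) and IL32 (3.25 ± 0.39, adjusted p = 0.00028) were higher in WT than in Null, and B2M (1.74 ± 0.24, adjusted p = 0.00066) in Mutant. The interferon list was higher in Mutant than in Null, with 7 members passing over all genes and 13 adjusted over the list alone (adjusted p = 7.64e-09, adjusted p = 0.0154 with an estimated correlation, and adjusted p = 0.133 with that and the GC slope). In WT it was higher by 0.23 (adjusted p = 0.00926, adjusted p = 0.206 with an estimated correlation). NF-kB targets were higher in WT by a median of 0.21 (adjusted p = 0.0185, adjusted p = 0.528 with an estimated correlation) and were not called in Mutant (adjusted p = 0.159). Antigen presentation was higher in Mutant by 0.61 (adjusted p = 3.29e-05, adjusted p = 0.358 with an estimated correlation) and was not called in WT (adjusted p = 0.0504). p53 targets were lower in Mutant than in Null by a median of -0.31 (adjusted p = 0.000175, adjusted p = 0.0196 with an estimated correlation, and adjusted p = 0.121 with that and the GC slope), with PLK2 at -1.80, and in WT the median was 0.25 (adjusted p = 0.073). Cholesterol genes were lower in both, at -1.0 in WT and -1.09 in Mutant (adjusted p = 2.98e-10 and 1.62e-07; adjusted p = 0.147 and 0.206 with an estimated correlation). SQLE (1.71 ± 0.30, adjusted p = 0.0065) went against its list in WT, while INSIG1 was at -2.32.

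Blood cell markers, led by ITGAM, CD74 and CD14 and present at a few CPM at most, rose after irradiation in all 3 lines. Their medians were 0.46, 0.69 and 0.64 in WT, Mutant and Null (adjusted p = 0.00877, 0.000433 and 0.00527; adjusted p = 0.204, 0.114 and 0.196 with an estimated correlation). CD74 went from 0.455 ± 0.235 to 2.49 ± 0.262 CPM in WT and from 0.639 ± 0.216 to 2.13 ± 0.167 CPM in Null. Mitochondrially encoded mRNAs were lower in the combination than after irradiation in Mutant, by a median of -0.39 (adjusted p = 0.000175, adjusted p = 0.437 with an estimated correlation).

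Libraries differed from each other mainly along gene GC content. The first principal component held 45.3% of the variance. Its relation to the GC slope of the libraries was r = 0.979 (rho = 0.976, n = 24) and r = 0.969 without the 2 farthest libraries. The permutation p was 1e-05 for r and for rho, the smallest the permutations can give (adjusted p = 2e-05 over 2 relations). Component and slope are computed from the same expression values, so this p does not show that the relation is particular to GC content. Slopes ran from -0.697 in Mutant solvent library 1 to 0.645 in Null combination library 2. They were lower in library 1 than in library 2 in every group but APR-246 in Null (0.153 and -0.0884). The slopes of the 4 treatments overlap, but their group means differed. Irradiation minus solvent was 0.29, 0.45 and 0.12 in WT, Mutant and Null. APR-246 minus solvent was -0.027, 0.24 and -0.018. The combination minus irradiation was -0.51, -0.21 and 0.078. Adding the GC slope can therefore change estimated effects as well as their spread. All gene calls made without the GC slope were kept when it was added. Of the 126 list calls 111 were kept, 13 were lost and 2 turned in sign.

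**Figure D4:**
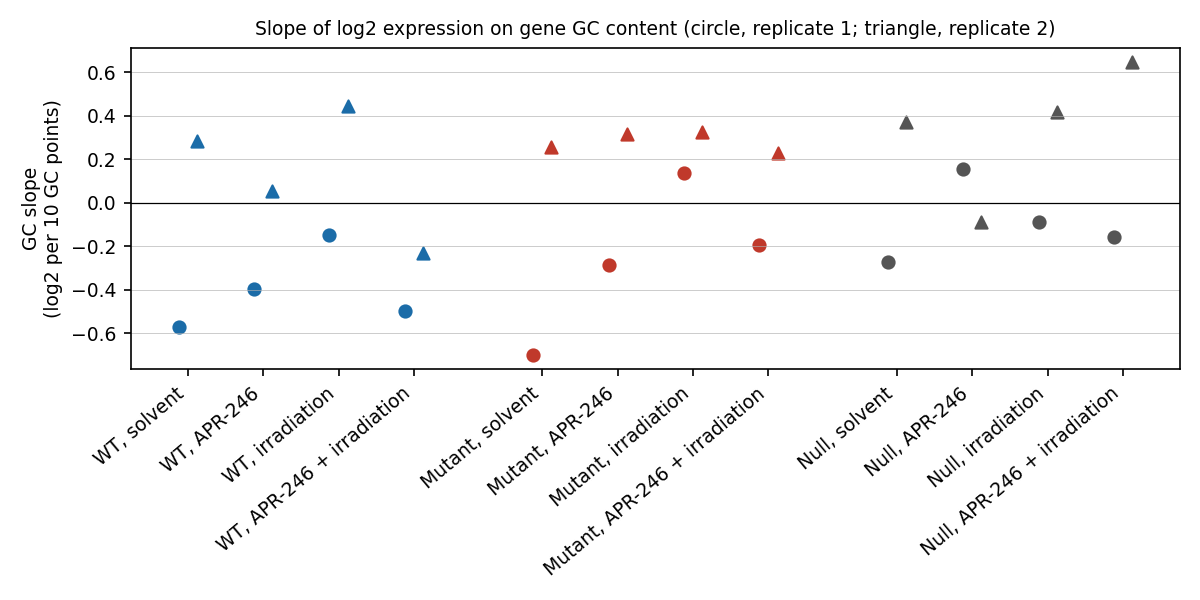
Slope of log2 values on gene GC percent in each library (circles library 1, triangles library 2), by group. Library 1 lies below library 2 in all groups but Null APR-246.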

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

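All tests of technical and biological explanations in this part were chosen after the result was seen. For dense cultures and for glucose use, the prediction was written before its test was run. The difference tests between lines and the additivity tests were planned, apart from those with the GC slope.

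A difference between lines singles out these results. In the test of WT minus Null after irradiation 6 genes had a difference above 0, and 229 had a difference in either direction with the GC slope. For Mutant minus Null the GC slope gave 1 gene, SPARC. For APR-246 it gave 2 genes for WT minus Null, CDKN1A and VSIR. The p53 target list differed for WT minus Null after APR-246 (adjusted p = 0.001731 with an estimated correlation), for Mutant minus Null after APR-246 (0.02568) and for WT minus Null after irradiation (4.424e-06). With the GC slope and an estimated correlation the first and the last held (adjusted p = 0.0241 and 0.000458) and the Mutant difference was lost (adjusted p = 0.0822).

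By list, the preset test called 5 differences for WT minus Null after APR-246 and 4 for Mutant minus Null. After irradiation it called 5 for WT minus Null and 6 for Mutant minus Null. For the combination against irradiation it called 1 (replication genes) and 4. Most of these were lost with an estimated correlation. ATF4 targets fell less in WT and in Mutant than in Null after APR-246, by 0.56 and 0.45 (adjusted p = 7.91e-05 and 0.00586; 0.609 and 0.705 with an estimated correlation). The WT part rests on WT APR-246 library 1, where the list stood -0.149 from the solvent mean, against -2.22 in library 2.

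The departure of the combination from the sum of both effects was called for 5 lists in WT, 6 in Mutant and 7 in Null by the preset test, and for none with an estimated correlation. For single genes 707 were called in Null with the GC slope, and 0 without Null irradiation library 1. ATF4 targets above the sum and replication genes below it recur in the 3 lines by the preset test (adjusted p = 0.434, 0.372 and 0.17, and 0.67, 0.204 and 0.576, with an estimated correlation). The ATF4 part largely mirrors the change after APR-246 alone, as the combination moved these targets little beyond irradiation. Within each line, the effect of APR-246, the effect of irradiation and the departure share the solvent libraries of that line. An unusual solvent culture would move all of them at once, but only in its own line.

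The first pattern weighed is the split of libraries along GC content. Depth does not explain it: total reads and the GC slope had r = -0.193 (rho = -0.185, permutation p = 0.36, n = 24). Gene length beyond GC explained 5.05% of the gene loadings of the first component, against 45.9% for GC beyond length. GC content bias stays open, with r = 0.979 between the component and the slope, though both come from the same expression values. A difference in library preparation is a candidate explanation. The labels record no preparation batch, and no biological explanation was tested.

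The second pattern is that the APR-246 libraries of WT are unlike each other. The spread of their difference is not removed with GC content: its SD was 0.437 on the log2 scale after GC correction, against at most 0.334 in the other groups. A swap with a WT solvent library would need a solvent library shifted like APR-246 library 2, but the WT solvent libraries differ from each other by 25% of that shift, a bound set after the values were seen. Library 1 shows 15% of the shift of library 2 over 945 genes, which is what untreated cells would give. Against that, its p53 targets stood 0.196 above solvent, close to 0.176 in library 2, and the shift itself is not specific to the compound (77.4 to 85.7% in irradiated WT libraries, measured from the same solvent mean), so a mislabelled or weakly dosed culture may be the source but is not shown.

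The third pattern is that ATF4 targets were on average highest in solvent, WT APR-246 library 1 apart. GC bias is not the cause, since the list median stayed at -1.18 or lower in all 6 treatment comparisons with the GC slope. Dense solvent cultures would lower YAP targets in solvent, but these were called higher under treatment in 1 of 6 comparisons. Exhausted glucose in solvent cultures would raise TXNIP and ARRDC4 under treatment, but 4 of 12 values were above 0. The signs of TXNIP decide little, as its standard errors with the GC slope were 0.92 to 0.96. ARRDC4 was below 0 in each comparison. With the GC slope limma called it lower after APR-246 in Mutant (-1.47, adjusted p = 0.0152) and Null (-1.49, adjusted p = 0.00467). Comparisons of a line share their solvent libraries. A candidate explanation that stays open is a weaker block of nonsense-mediated decay under treatment. Spliced hosts of small nucleolar RNAs, its usual targets, were called lower in 6 of 6 comparisons. That list left out SNHG8 and EPB41L4A-AS1, which had prompted it. None of these calls held with an estimated correlation (adjusted p = 0.105 to 0.184). The comparisons of each line share their solvent libraries, so they are not independent. A fall of these hosts beside ATF4 targets cannot tell a cause of the ATF4 pattern from a change that goes with it. The amino acid supply of the cultures was not measured.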

How the results depend on the processing

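All GC settings, the pseudocounts, CPM without TMM factors and the crossed replicate numbers were added after seeing the data. edgeR on recovered reads under its present defaults is the test planned first, and its place as an alternative was set after seeing the data. The other alternatives were fixed before the data were examined. Values are numbers of genes called in both directions unless another quantity is named, and the cause of a change was not tested unless given.

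Of the alternative counts of genes, 309 stayed within 1.5 times the main count and 160 did not (with the GC slope and 1 library left out, 51 and 65). Of the overlaps and correlations 86 stayed and 71 moved. Named genes kept direction and call in 953 cases and lost the call in 216, none reversing (377 and 171 with the GC slope). Lists kept their call in 370 cases, lost it in 132 and reversed in 2. Both reversals came with the GC slope in the WT combination against irradiation: homologous recombination (adjusted p = 0.4322) and antigen presentation (adjusted p = 0.7974). With RLE scaling all counts stayed within 1.5 times.

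With DESeq2 APR-246 gave 101 in Mutant and 456 in Null, irradiation 822, 598 and 733 in WT, Mutant and Null, the WT combination 1, Null beyond additive 26, WT minus Null irradiation 20, and the solvent lines 464 and 962. Its overlaps, higher and lower, were 29 and 38 for APR-246 in Mutant and Null, and for irradiation 101 and 154 (WT and Mutant), 121 and 188 (WT and Null) and 120 and 162 (Mutant and Null).

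edgeR quasi-likelihood on recovered reads gave 6 for APR-246 in Null, 5 and 73 for irradiation in Mutant and Null, and 0 for WT minus Null irradiation. Its irradiation overlaps were 1 higher for WT and Mutant, 13 higher for WT and Null, and 3 higher and 0 lower for Mutant and Null. The legacy version gave 4 for APR-246 in Null, 100, 3 and 18 for irradiation, and 0 for WT minus Null irradiation.

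The GC slope as covariate removes spread that GC content explains and can shift effects where group mean slopes differ. With it APR-246 gave 1413 in Mutant and 3101 in Null. Irradiation gave 3724, 2786 and 4133, Null beyond additive 707, WT minus Null 2 for APR-246 and 229 for irradiation, Mutant minus Null irradiation 1, and the solvent lines 1788 and 3264. Overlaps were 436 and 509 for APR-246 in Mutant and Null, and for irradiation 570 and 937, 706 and 1102, and 665 and 1084. The Mutant correlation of compound effects became 0.267. With an estimated correlation 3 list tests held under this setting, and 9 of the 126 without it.

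edgeR with the GC slope gave 1380 and 3143 for APR-246 in Mutant and Null and 3765, 2876 and 4162 for irradiation. It gave 1 for the WT combination, 705 for Null beyond additive, 10 and 202 for WT minus Null (APR-246, irradiation), 2 for Mutant minus Null irradiation, 1795 and 3386 for the solvent lines, and a Mutant correlation of 0.249. Removing the GC and length trends gave 403 for APR-246 in Null, 761, 381 and 781 for irradiation, 15 for WT minus Null irradiation and 465 and 1072 for the solvent lines.

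With replicate numbers as a block, APR-246 gave 299 in Mutant and 567 in Null, irradiation 1611, 2416 and 1305, Null beyond additive 2, WT minus Null irradiation 20, and the solvent lines 568 and 1501. A block per line gave 57 and 305, then 1249, 1692 and 951, then 18, and 403 and 991. With the block and the GC slope APR-246 gave 2233 and 3321, irradiation 3874, 2701 and 4452, Null beyond additive 764, WT minus Null 2 and 229, Mutant minus Null irradiation 0, the solvent lines 1695 and 2929, and the Mutant correlation 0.204. The numbers pair libraries across groups: of 66 pairs of groups, 11 had replicate differences with r below 0 (lowest -0.562), all with APR-246 in Null, and the lowest without it was 0.384. Crossing the numbers of that group under the block per line gave 316 higher and 477 lower genes (793).

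Without a filter on low counts APR-246 gave 39 in WT and 14 in Mutant, Mutant irradiation 65, the combination against irradiation 30, 28 and 58, beyond additive 5, 5 and 9, WT and Mutant minus Null 2 and 2 (APR-246), 14 and 11 (irradiation) and 12 and 16 (combination). A stricter filter gave 40 for Mutant irradiation and 2 for WT minus Null irradiation. Using the libraries of the compared lines alone, which leaves fewer samples, gave 0, 0 and 28 for irradiation and 0 for WT minus Null irradiation. A pseudocount of 0.1 gave 6 for APR-246 in Null, 82 for Null irradiation and 0 for WT minus Null irradiation; a pseudocount of 2 gave 1 and 51 for APR-246 in Mutant and Null, 56 and 215 for irradiation in Mutant and Null, 4 for Null beyond additive and 15 for WT minus Null irradiation. CPM without TMM factors gave 1 for APR-246 in Null and 54 for Mutant irradiation.

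Leaving out 1 library at a time, with the lone library assumed to vary like the other groups, gave 0 to 132 for APR-246 in WT, 0 to 8 in Mutant and 0 to 5 in Null; 67 to 155, 0 to 2 and 1 to 12 for irradiation; 0 to 47 for the WT combination; and 0 to 21, 0 to 3 and 0 to 1 beyond additive. Differences ran from 0 to 3 (WT minus Null APR-246), 0 to 2 (Mutant minus Null APR-246), 0 to 31 and 0 to 1 (irradiation) and 0 to 22 (WT minus Null combination). The solvent lines gave 104 to 157 and 202 to 368. Irradiation overlaps were 0 to 0 (WT and Mutant, higher), 1 to 9 and 0 to 13 (WT and Null), and 0 to 2 and 0 to 0 (Mutant and Null). Correlations ran from -0.743 to 0.739 (WT), -0.497 to 0.428 (Mutant) and -0.218 to 0.396 (Null). With the GC slope counts moved as well, among them 1552 higher and 1300 lower genes for APR-246 in WT without its library 1, and 0 for APR-246 in Mutant without library 2 of solvent or of APR-246.

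At this depth a gene with fewer than 3 reads in a library (0.0517 to 0.0564 CPM) is not distinguished from one with none.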

Other observations

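The lists of WNT targets, YAP targets and small nucleolar RNA hosts were added after seeing the data. Genes of the first and last had been seen by then, so tests of those lists came after the result; the YAP list was written for the test of dense cultures, whose prediction was set before that test was run.

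WNT targets were higher after APR-246 alone and after irradiation alone in each line by the preset test. No call of the full list held with an estimated correlation (adjusted p = 0.105 to 0.235). Over all genes 0, 0 and 1 members rose after APR-246 in WT, Mutant and Null, and 1, 0 and 1 after irradiation. In Null BMP4 was called higher after each treatment, as was, with the GC slope, AXIN2, a feedback inhibitor of the pathway. Without AXIN2, SP5 and BMP4, the genes seen first, list medians were 0.24, 0.46 and 0.62 after APR-246 in WT, Mutant and Null (adjusted p = 0.0254, 0.00148 and 0.00126). After irradiation they were 1.05, 0.50 and 0.64 (adjusted p = 1.18e-06, 0.000937 and 0.00178). With an estimated correlation these adjusted p values were 0.105 to 0.372. In the WT combination the list was lower than after irradiation, by a median of -0.70 (adjusted p = 7.22e-06, 0.117 with an estimated correlation; median -0.315 with the GC slope, adjusted p = 0.000479), and it lay below the sum of both effects in WT, Mutant and Null (adjusted p = 5.24e-07, 0.00173 and 0.00972; 0.105, 0.222 and 0.305 with an estimated correlation). Spliced hosts of small nucleolar RNAs were lower after APR-246 alone and after irradiation alone. Without SNHG8 and EPB41L4A-AS1 their medians were -0.44, -0.88 and -0.96 after APR-246 (adjusted p = 0.00251, 1.53e-05 and 3.1e-05) and -0.95, -1.04 and -0.82 after irradiation (adjusted p = 4.61e-05, 4.56e-05 and 8.36e-06), with 0.105 to 0.184 for an estimated correlation. They lay above the sum of both effects in the combination (adjusted p = 0.015, 0.000589 and 0.00122, and 0.261, 0.154 and 0.172 with an estimated correlation). The combination against irradiation did not call these hosts, so that departure largely mirrors their fall after APR-246.

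YAP targets set Null apart from the other lines by the preset test. In solvent they were lower in WT than in Null by a median of -0.38 (adjusted p = 1.7e-08, 0.0792 with an estimated correlation), with 5 members called lower, CCN2 among them, and lower in Mutant than in Null by -0.21 (adjusted p = 7.97e-05, 0.105 with an estimated correlation), also with 5 members called lower and 1 higher. After irradiation they rose in WT by 0.48 (adjusted p = 0.00664, 0.184 with an estimated correlation) and were lower in Null by -0.22 (adjusted p = 0.0355, 0.261 with an estimated correlation and 0.0939 with the GC slope). The difference between both responses was 0.61 (adjusted p = 2.13e-07, 0.0939 with an estimated correlation), and for Mutant minus Null it was 0.12 (adjusted p = 0.00463, 0.172 with an estimated correlation).

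In simulated data with 2 libraries per group, 2-fold changes were rarely recovered without the GC slope (1%) and mostly recovered with it (84%). Those data were drawn from the GC slope model itself, so they cannot show whether that model suits the real libraries.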
